A study of Rattus norvegicus with 6 samples.

How the data were processed

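Total RNA from 6 rat kidney graft samples, 3 from recipients given AMD3100 and 3 from recipients given saline, was hybridised to 1-colour (Cy3) Agilent arrays, 1 sample per array. Groups and replicate numbers were taken from the sample titles. The deposited scanner files hold spot intensity on a linear scale. Per the file headers, they were made with Agilent Feature Extraction 11.5.1.1, while the submitters' processing notes name version 10.7.1.1. Per the file headers, the processed signal is background-subtracted and detrended within each array, and it is not scaled between arrays. The median signal and median local background are raw intensity, per the file headers. The deposited log2 values give, for every array, the same log2 processed signal shifted by a constant. Against the scanner values, r was 1.000 on every array, 100% of probes lay within 0.01 of that constant, and the 75th percentile was 0. Their scale, centring and direction are known from this comparison, and their medians per array lay between −2.01 and −1.88. The headers name genome build rn4 for the array design.

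Each array held 62976 spots. Control spots (1439) were left out of the comparison, as were spots marked as non-uniform or population outliers, and the spots of the 9263 probes printed in duplicate were averaged. A further 64 probes had no unmarked spot on at least 1 array and were left out, which leaves 52210. Since 68.1% of the probes or more were detected on each array, each array's log2 processed signal was shifted by its 75th percentile over all non-control probes. That percentile was 482, 401 and 507 intensity units on AMD3100 replicates 1, 2 and 3, and 612, 579 and 657 on saline replicates 1, 2 and 3. The log2 SD between duplicate spots of a probe was 0.119 to 0.183. No spot was saturated. A probe was tested if it was well above background on at least 3 of the 6 arrays whatever their group (39758 probes), and 8549 probes were above background on no array. A probe not above background on any array of a group has only a bound there, and its fold is given as at least that value. Such a bound holds for this processing and leaves out sampling error.

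The files pair the catalogue probes with no gene name, and no table used here does so. Tests were therefore run per probe, not per gene as planned, and the gene lists and the genes named in advance could not be tested, since 0 of 755 list members had a named probe. RefSeq accessions were matched without version numbers to current rat gene records of assembly GRCr8. Of 6299 RefSeq-named probes, 524 matched a single gene. Since that assembly differs from the build of the design, only names and neighbouring genes were taken from it, and no coordinates are given.

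AMD3100 was compared with saline by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate), with Benjamini-Hochberg correction over all tested probes and a threshold of 0.05. A second, uncorrected count took probes at an unadjusted p below 0.05 and at least 2-fold. Probe classes were tested with camera at a preset correlation of 0.01 and with an estimated correlation. These class tests, and corrections over a class or over the matched probes alone, were chosen after seeing the data. Single control measures were compared by an exact permutation test, two-sided, whose smallest p is 0.1 with 3 against 3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and the files were read with the data.table package, version 1.17.8.

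The rule for named transcripts, set before the data were examined, took 12 fixed genes, up to 12 transcripts in each direction with a symbol other than a LOC or RGD name that differed at least 2-fold without overlap, 3 members of each called gene list and of 5 fixed lists, and the 3 non-coding probes with the lowest p in each direction. The last part gave 6 transcripts and the other parts gave none. At most 2 unnamed catalogue probes are given per direction. All probes with a symbol that is not a LOC or RGD name were then described, as was every matched transcript with a 2-fold difference and no overlap.

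The comparison was tested on simulated data: values for the 39758 probes were drawn from their real means and residual SDs, and 200 probes were changed in each of 10 runs. Of probes changed 2-fold, 4-fold, 8-fold and 16-fold, 5.20%, 58.4%, 78.6% and 88.8% were recovered at an adjusted p below 0.05 in this comparison of 3 against 3. On average 5.1 unchanged probes were called per run, and no recovered probe had the wrong sign. Noise was drawn independently for each probe, with the same SD on all arrays, so deviations shared by many probes of a real array were left out. Of the unchanged probes 5.25% had an unadjusted limma p below 0.05, against 13.8% of the tested probes in the real data. The shares recovered therefore hold for the simulated setting.

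Saline replicates 1 and 3 were checked for being 1 RNA sample on 2 arrays. Over 2244 bright probes in duplicate, the difference between these arrays at 1 spot correlated with that at the other spot at r = 0.518, so it exceeded spot noise, though less than for any other pair of arrays (lowest other r = 0.796). A labelling or hybridisation difference would also repeat at both spots, so this check cannot tell 2 grafts from 1 RNA on 2 arrays. Saline replicates 1 and 3 were kept as 2 samples, as labelled. The alternatives planned before the data were examined were quantile normalization, normexp background correction, another set of probes for the percentile, no filter or a filter on all 6 arrays, the deposited log2 table, blocks for replicate number and slide row, leaving out each array, eBayes with trend and robust, and array weights. The normexp alternative, with an offset of 50, used the median in place of the mean spot signal, which was not used here. Alternatives added after seeing the data were the share of detected probes as a covariate, the mean of saline replicates 1 and 3 as 1 sample, scaling to the mean of the 7 E1A spike-in probes above background on all arrays, and the second slide row alone.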

Results

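Kidney grafts from a rat model of chronic allograft nephropathy were profiled 12 weeks after transplantation. In this model a kidney from a male Fisher donor is placed in a Lewis recipient, and the graft scars slowly. AMD3100 (plerixafor), a small-molecule antagonist of the chemokine receptor CXCR4, was given under the skin at 1 mg per kg per day to 1 group, and saline was given to the other. Each group had 3 graft samples, and each was hybridised to its own 1-colour array carrying mRNA and long non-coding RNA (lncRNA) probes, so 6 arrays lay on 1 slide. The comparison asks which transcripts differ between AMD3100-treated and saline-treated grafts. The labels call the replicates separate samples without naming the animals, so p-values measure the spread between these samples.

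Of 52210 probes analysed, 39758 were well above background on 3 or more arrays and were tested, and the number of arrays limits the precision. The share of probes well above background was 68.1%, 72.6% and 72.7% on AMD3100 replicates 1, 2 and 3, and 79.4%, 74.3% and 81.1% on saline replicates 1, 2 and 3. All AMD3100 arrays lay below all saline arrays (71.1% ± 2.60 against 78.3% ± 3.55, SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 allows). The probes fall into classes by their names. Agilent catalogue probes, 24566 of those tested, mostly stand for mRNA and carry no gene name in the files. The 15192 other probes stand for non-coding transcripts of the NONCODE collection (11470), RefSeq non-coding transcripts (3507), transcripts of ultraconserved elements (195) and a small remainder (20).

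The non-coding transcripts with the lowest p values in each direction differed by at least 2.11-fold, and none passed correction over all probes. NONRATT015587 was lower under AMD3100, with a log2 signal relative to the array's 75th percentile of −1.97 ± 0.15 against −0.08 ± 0.04 in saline grafts (SD, n = 3 each), a log2 difference of −1.88 ± 0.18 (SE; limma adjusted p = 0.265). XR_361469.2, the lncRNA LOC102551612, was not well above background on any AMD3100 array and was at least 2.73-fold lower there than in saline grafts (limma adjusted p = 0.306). Its nearest protein-coding genes are Smad4, the shared Smad of TGF-beta and BMP signalling, and Elac1, which encodes a tRNA-processing enzyme. NONRATT025109, also not well above background on any AMD3100 array, was at least 3.31-fold lower (limma adjusted p = 0.306). With normexp the log2 differences of LOC102551612 and NONRATT025109 were −0.26 and −0.24, and that of XR_347830.2 below was 0.80. The normexp offset shrinks differences of dim probes, but the signal used changed as well, and their shares were not tested. In the other direction, NONRATT023184, a bright probe, stood at 3.67 ± 0.34 under AMD3100 and 1.95 ± 0.52 in saline grafts, a log2 difference of 1.72 ± 0.32 (SE; limma adjusted p = 0.323). NONRATT002947 was higher by 1.08 ± 0.19. XR_347830.2 was not well above background on any saline array and was at least 2.78-fold higher under AMD3100; the limma adjusted p of both was 0.323. With scaling to the spike-in spots the log2 differences of NONRATT023184, NONRATT002947 and XR_347830.2 were 1.08, 0.44 and 0.84. For each of these 6 transcripts, the 3 AMD3100 values all lay on one side of the 3 saline values. Their choice by lowest p favours this, and it held for 20.0% of all tested probes. These bounds set the bright group's mean against the dim group's mean, each dim array taken at the higher of its own value and the lowest signal among its probes well above background. They hold for this processing only and are not confidence limits, and normexp or spike-in scaling gave smaller differences where printed above. For XR_347830.2 the bound equals the plain fold between the group means.

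**Figure D1:**
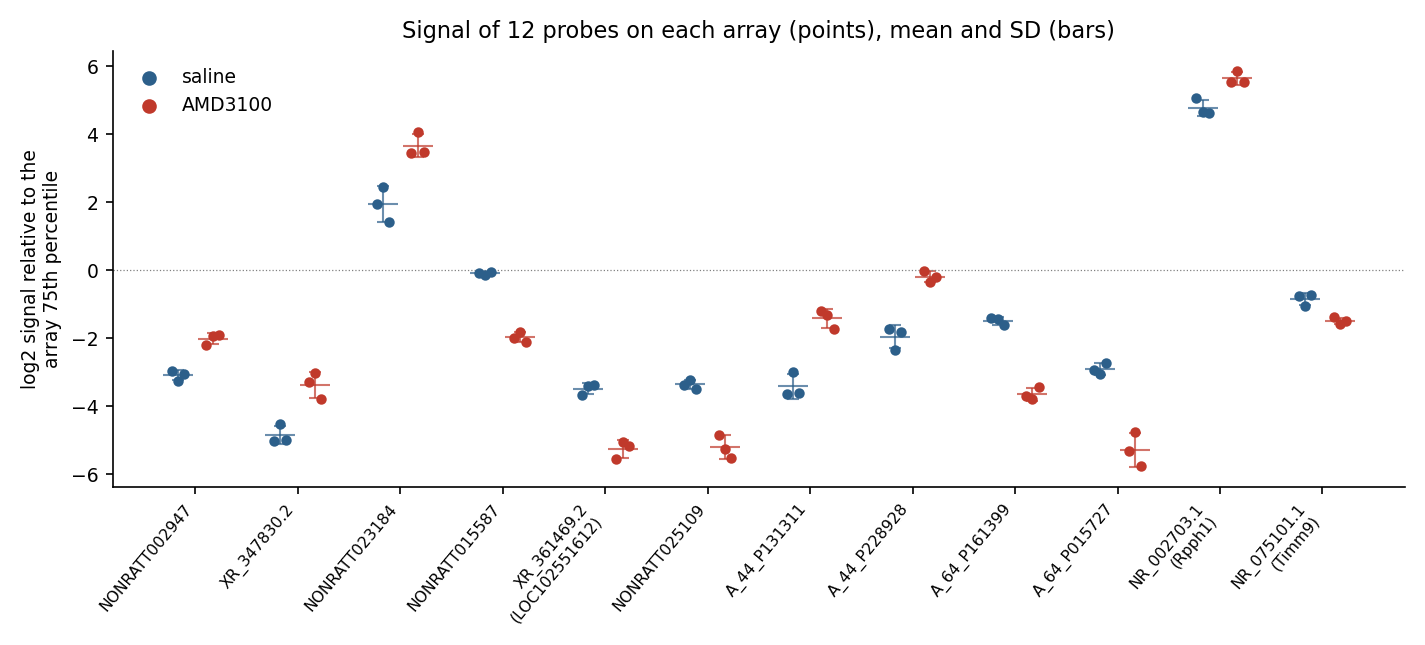
Log2 signal relative to each array's 75th percentile (vertical axis) for 12 probes (horizontal axis): 6 non-coding transcripts, 4 catalogue probes, and Rpph1 and Timm9. Points are single arrays and bars the mean and SD of 3 grafts. For all 12 probes the AMD3100 points lie on one side of the saline points, as for Rpph1, between 5.53 and 5.88 against 4.62 to 5.06. The probes were picked for a low p or for this lack of overlap, which held for 20.0% of all tested probes.

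Among RefSeq transcripts with a current gene symbol, Rpph1, the RNA component of ribonuclease P that trims tRNA precursors, was higher under AMD3100 in 3 of 3 grafts. Its log2 signal was 5.65 ± 0.20 against 4.78 ± 0.24 (SD, n = 3 each), a log2 difference of 0.87 ± 0.21 (SE; limma adjusted p = 0.323 over all probes), which was 0.24 with scaling to the spike-in spots. A non-coding variant of Timm9, which encodes a chaperone of the mitochondrial intermembrane space, was lower in 3 of 3 grafts, by a log2 difference of −0.65 ± 0.19 (limma adjusted p = 0.323; −0.40 with normexp). Adjusted over the 18 probes of 17 such symbols alone, the p-values were 0.0798 and 0.0916, so neither passed. The lncRNA Cb707485 differed by −1.37 ± 0.71, with AMD3100 values that overlapped those of saline grafts, and by −0.52 without AMD3100 replicate 1. The remaining symbols in this set were Pincl, Abhd11-as1, Oip5-as1, Vof16, Miat, Jpx, Lnc081, Aptr, Lnc134, Chchd4l1, Meg3, Lnc004, Tox3l1 and Prrc2c, and for each of them the groups overlapped. Meg3, an imprinted lncRNA, differed by 0.13 ± 0.35, Miat by −0.16 ± 0.26 and Jpx, a lncRNA of the X-inactivation centre, by 0.10 ± 0.24. The interval of such differences is wide, so they do not show equal levels.

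Of the 259 tested RefSeq probes with any symbol, LOC names included, 10 differed at least 2-fold at an unadjusted p below 0.05, 1 higher and 9 lower. In 8 of these the groups did not overlap, and these 8 were singled out after their values were seen. LOC102551612 alone passed when corrected over the 259 probes alone (limma adjusted p = 0.0178). LOC102548512 was the one higher transcript, with a log2 difference of 1.01 ± 0.25 (0.37 with scaling to the spike-in spots). LOC102547708, between Hdgfl1 and Nrsn1, was lower by a log2 difference of −2.62 ± 0.68, and its saline values spread widely (−0.06 ± 1.51, SD, n = 3). With the share of detected probes as a covariate it differed by −0.68. That share parted the groups without overlap, so the covariate can take up part of the group difference itself. LOC102549197 lies next to Uqcrb, a gene for a subunit of respiratory complex III, and was at least 3.70-fold lower (log2 difference −0.60 with normexp and −0.98 with that covariate). LOC102549660, next to the adrenergic receptor gene Adra1b, differed by −1.05 ± 0.27. LOC102549737, LOC102549869 and LOC102554996 differed by −1.74 ± 0.54, −1.39 ± 0.47 and −1.05 ± 0.37. With the covariate these were −0.66, −1.46 and 0.016, and with normexp −0.39, −0.55 and −0.15, while LOC102549660 fell to −0.66 with normexp. The limma adjusted p of these 8 over all probes lay between 0.306 and 0.336.

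Catalogue probes were not paired with gene names here, so the 12 genes fixed in advance, among them Cxcr4, Cxcl12, Tgfb1 and Col1a1, and the 30 gene lists for immune cells, nephron segments, matrix and injury were not tested. The catalogue probes with the lowest p values and no overlap were A_64_P161399 (log2 difference −2.16 ± 0.19, and −1.09 with normexp), A_64_P015727 (at least 4.38-fold lower, not well above background on any AMD3100 array, log2 difference −0.57 with normexp), A_44_P131311 (2.00 ± 0.26, and 1.27 with normexp) and A_44_P228928 (1.76 ± 0.23, and 1.13 with scaling to the spike-in spots). Their limma adjusted p was 0.265, 0.306, 0.306 and 0.306.

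Over all 39758 probes, limma called 0 at an adjusted p below 0.05, the smallest adjusted p being 0.265, while 5498 (13.8%) had an unadjusted p below 0.05. At that unadjusted level, 1734 probes differed at least 2-fold, 463 higher and 1271 lower under AMD3100. This split depended on the scaling and the filter: it was 56 higher and 7610 lower when arrays were scaled to spike-in spots, and 981 higher and 1655 lower with no filter on dim probes. The groups did not overlap for 20.0% of the probes, against 10% by chance for 3 against 3, an average over all splits of the arrays. Probes are not independent, and a single split can lie far from such an average. The split of AMD3100 replicate 1 with saline replicates 1 and 3 against the rest gave 5176 probes at an unadjusted limma p below 0.05. Non-coding transcripts gave 0 adjusted calls and 2034 at an unadjusted p below 0.05. Of these, 737 differed at least 2-fold, 100 higher and 637 lower (86.4% lower), against 363 higher and 634 lower (63.6% lower) among the catalogue probes. The non-coding share was 70.3% with no filter (369 higher, 874 lower) and 68.2% with the share of detected probes as a covariate (147 higher, 315 lower), where the catalogue shares were 56.1% and 59.6%. Without AMD3100 replicate 2 it was 77.3% (145 higher, 494 lower), close to the catalogue share of 70.8%. By class, 438 of the 510 such NONCODE transcripts, 187 of the 214 RefSeq non-coding transcripts and 12 of the 13 ultraconserved transcripts were lower. As whole classes, none passed camera against the other probes. With the preset correlation the closest was the ultraconserved class (camera adjusted p = 0.0564, and 0.643 with an estimated correlation). With an estimated correlation the closest was the catalogue class, in the higher direction (camera adjusted p = 0.245). One ultraconserved transcript, uc.437, passed when corrected over its class of 195 alone (log2 difference −1.48 ± 0.19 SE, limma adjusted p = 0.0188, and 0.306 over all probes).

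**Figure D2:**
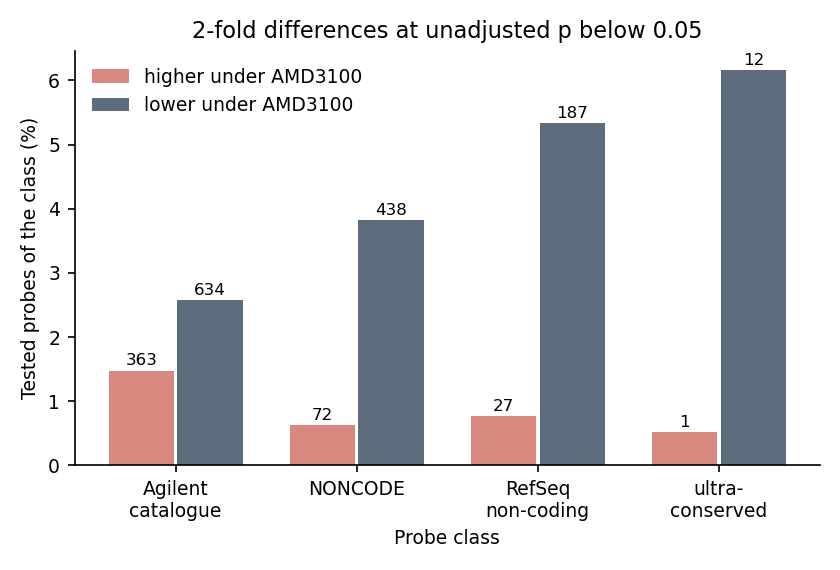
Percent of the tested probes of each class (vertical axis, from 0) that differed at least 2-fold at an unadjusted p below 0.05, higher or lower under AMD3100, by probe class (horizontal axis); numbers over the bars are probes. In each of the 4 classes more probes were lower than higher, for example 438 against 72 NONCODE probes.

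Leaving out saline replicate 2 gave 210 adjusted calls (109 higher, 101 lower) and 3713 2-fold differences, and catalogue probes were then nearly balanced (1151 higher, 1189 lower) while 72.9% of non-coding differences were lower. For 195 of the 210 calls the array left out lay nearer the AMD3100 mean than the mean of the other saline arrays. No probe passed with all arrays in, so these calls were picked in part for that position. The count is therefore no separate evidence on that array. Leaving out saline replicate 1 or saline replicate 3 gave 0 adjusted calls and 1016 or 742. Weighting arrays by how closely they follow their group gave 5023 adjusted calls and a like balance of catalogue probes (1138 higher, 1174 lower). The lowest weights fell on AMD3100 replicate 1 (0.224) and saline replicate 2 (0.423). The log2 SD between duplicate spots was 0.183 on AMD3100 replicate 1, the highest, but 0.145 on saline replicate 2, below the 0.156 of saline replicate 1. A low weight on saline replicate 2 acts in part like leaving it out.

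The arrays did not part cleanly by group. Across tested probes, which are not independent replicates, saline replicates 1 and 3 were the most alike (Pearson r = 0.990), and AMD3100 replicates 2 and 3 followed (r = 0.980). Saline replicate 2 correlated better with AMD3100 replicate 3 (r = 0.976) and AMD3100 replicate 2 (r = 0.966) than with saline replicates 1 and 3 (r = 0.949 with each). AMD3100 replicate 1 stood apart, with r between 0.899 and 0.942 to the other arrays. AMD3100 and saline replicate 1 lay in the first row of the slide and the other 4 arrays in the second. With the row as a block, limma gave 0 adjusted calls, 5134 probes at an unadjusted p below 0.05 and 1781 2-fold differences. Within the second row alone it gave 0, 4106 and 1359. The first row held 1 array of each group and gives no test.

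**Figure D3:**
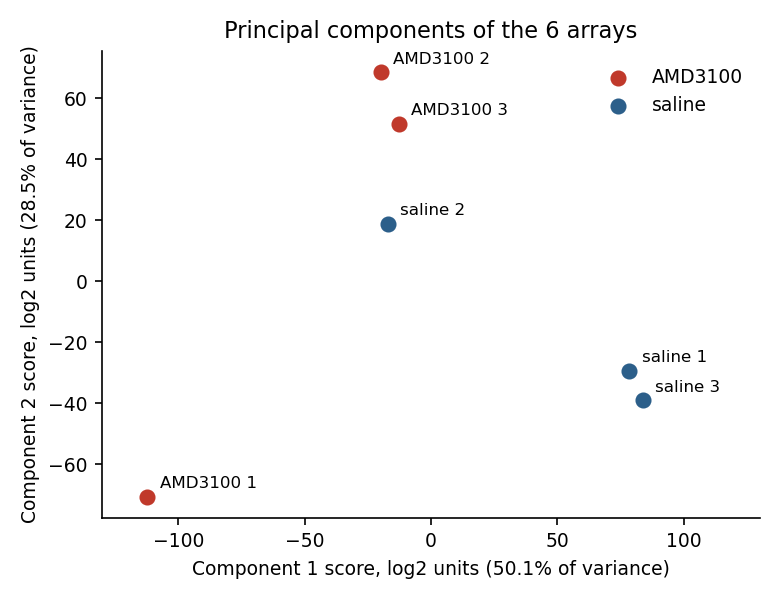
Scores of the 6 arrays on the first component (horizontal axis, 50.1% of the variance) and the second (vertical axis, 28.5%), in log2 units over 39758 probes; each point is 1 array, coloured by group. Saline 2 (−17.1 and 18.9) lies nearer AMD3100 2 and AMD3100 3 than saline 1 and saline 3, and AMD3100 1 lies apart.

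Control spots on the same arrays gave measures of labelling and RNA quality beside these differences. The 3′ over 5′ log2 signal of the housekeeping gene Pgk1, a ratio that rises as RNA is shortened, was 3.49 ± 0.03 on AMD3100 arrays and 3.27 ± 0.23 on saline arrays, without overlap (SD, n = 3 each; exact permutation test, two-sided p = 0.1). Without saline replicate 1 (3.01) the difference fell from 0.23 to 0.10, and the control spots for human and mouse Pgk1 overlapped between the groups. For Gapdh it was 0.44 ± 0.31 and 0.42 ± 0.20 and overlapped (exact permutation test, two-sided p = 0.9).

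**Figure D4:**
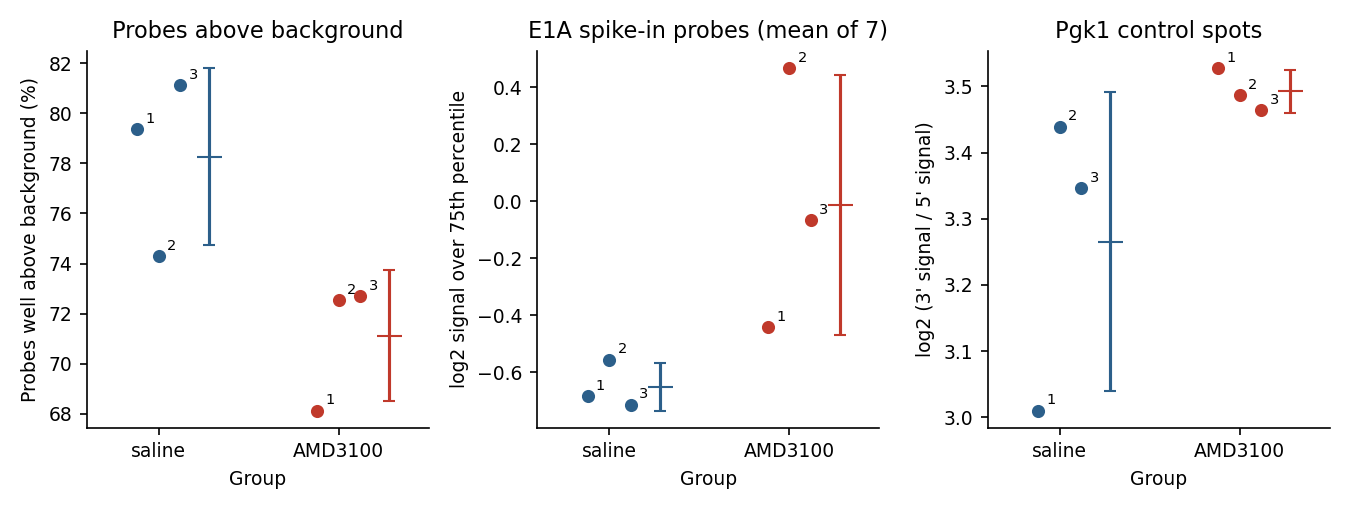
Probes well above background in percent (left), mean log2 signal of the 7 E1A spike-in probes above background on all arrays, relative to the 75th percentile (middle) and log2 3′ over 5′ signal of the Pgk1 spots (right), by group; points are arrays marked with their replicate number, bars the mean and SD of 3, and the vertical axes do not start at 0. The plotted values do not overlap between the groups in any panel, with 71.1% against 78.3% of probes above background.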

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

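Leaving out single arrays and array weights were planned before the data were examined, while the tests of control spots, brightness, labels and detection below were chosen after the results were seen. Control spots outside the comparison differed between the groups. The E1A spike-in spots detect adenoviral transcripts added in fixed amounts during labelling, and 7 of their 10 probes were above background on all arrays. The mean of these 7 lay 0.64 higher on the log2 scale on AMD3100 arrays relative to the 75th percentile (−0.01 ± 0.46 against −0.65 ± 0.08, SD, n = 3 each; every AMD3100 array above every saline array, exact permutation test, two-sided p = 0.1, the smallest possible). Single probes differed by 0.22 to 0.88, 5 of the 7 parted the groups without overlap, and the mean difference was 0.40 without AMD3100 replicate 2. The Pgk1 control spots had a 3′ over 5′ log2 signal 0.23 higher on AMD3100 arrays, again without overlap (exact permutation test, two-sided p = 0.1), but only 0.10 higher without saline replicate 1. In the control spots for human and mouse Pgk1 on the same arrays the groups overlapped (0.20 and 0.22 higher; exact permutation test, two-sided p = 0.6 and 0.4).

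The first pattern is the excess of lower values under AMD3100 among the 2-fold differences, 1271 of 1734 (73.3%), which ranged from 59.0% without saline replicate 2 to 75.5% over the other alternatives, and was 99.3% (56 higher, 7610 lower) when arrays were scaled to the spike-ins above, so its size depends on the scaling. One candidate explanation is that fewer probes were detected on the AMD3100 arrays. The share that was lower was 81.0% in the dimmest and 59.7% in the brightest of 4 equal groups of probes ranked by mean signal (exact binomial 95% interval 53.6% to 65.6%, which treats probes as independent). The excess was therefore smaller in the brightest probes. It came mostly from non-coding probes there (52 lower, 13 higher), while catalogue probes were nearly balanced (108 lower, 95 higher). Detection and group cannot be told apart, since every AMD3100 array detected fewer probes than every saline array. RNA less intact in the AMD3100 grafts also stays open, since the Pgk1 ratio was 0.23 higher on average without overlap (closest arrays 3.46 against 3.44) but the Gapdh ratio overlapped, and a biological effect of the drug on these transcripts stays open and untested beside it.

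The second pattern is that saline replicate 2 correlates better with AMD3100 replicates 2 and 3 than with the other saline arrays, though not with AMD3100 replicate 1 (r = 0.942, against 0.949 with each saline array). Exchanged labels within the series would need a partner, and 0 AMD3100 arrays correlated better with saline replicates 1 and 3 than with the other AMD3100 arrays. Its own detection level was 74.3%, between the AMD3100 arrays and the other saline arrays, so an effect of detection cannot be told apart from one of the graft. A single wrong label, an exchange with a sample outside the series and a true difference between saline grafts, such as in the degree of scarring, stay open and were not tested. Without this array, limma gave 210 adjusted calls, of which 148 had an unadjusted p below 0.05 over all 6 arrays. In 195 of the 210, saline replicate 2 lay nearer the AMD3100 mean than the mean of the other saline arrays. Calls that pass only without this array are picked in part for that position, so the count adds no separate evidence on it.

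The 6 arrays can be split into 3 and 3 in 10 ways, too few for any count to fall under a share of 0.05. The real split gave 1734 2-fold differences and the highest other split 1575, so 1 of the 10 splits gave as many. For non-coding probes the values were 737 and 664, again 1 of 10. At the adjusted threshold the real split gave 0 calls (5498 at an unadjusted p below 0.05). The highest other split gave 5 (5176 at that unadjusted level), a comparison that cannot be informative for a count of 0. With array weights, the real split gave 5023 adjusted calls but the highest other split 13864, and 3 of the 10 splits gave as many. The weights of that highest split did not converge, and the next gave 10994. Without saline replicate 2, the 5 arrays also make only 10 splits into 3 and 2. The real one gave 210 adjusted calls and the highest other 1, so 1 of 10 gave as many. This comparison favours the real split, since the saline array left out was the one most like the AMD3100 arrays. Only the real split also makes the 2 most alike arrays, saline replicates 1 and 3 (r = 0.990), the group of 2.

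Probes above background on all 3 saline arrays and on no AMD3100 array numbered 520, and 7 showed the opposite, while the highest such count in 1 direction among the other splits of the arrays was 315.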

How the results depend on the processing

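Some alternatives were chosen after seeing the data: the detection covariate, the mean of saline replicates 1 and 3, spike-in scaling and the second slide row alone. In order, values are adjusted calls, adjusted non-coding calls, 2-fold differences and non-coding 2-fold differences, which were 0, 0, 1734 and 737 as reported. Leaving out 1 array gave 0 to 210, 0 to 52, 742 to 3713 and 335 to 1373. The highest values came without saline replicate 2 and the lowest 2-fold counts without saline replicate 3 (1016 and 457 without saline replicate 1). Array weights gave 5023, 1740, 3712 and 1400. Spike-in scaling, which moved the median difference of all probes from 0.03 to −0.60, gave 27, 11, 7666 (99.3% lower) and 3379. The other alternatives gave 0 adjusted calls in limma, with 1485 to 7817 probes at an unadjusted p below 0.05. Among these, the 2-fold counts were 773 and 255 with normexp (median difference 0.12), 2636 and 1243 with no filter, 1134 and 391 for probes above background on all 6 arrays, 1142 and 462 with the detection covariate, and 832 and 376 with the averaged saline replicates. The filters change how many probes are tested, and averaging leaves fewer samples; for the rest the cause was not tested. Of the 1734 probes, 1624 again met both the 2-fold and the unadjusted p criterion without saline replicate 2, 718 without saline replicate 3 and 158 with the detection covariate.

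With the replicate number as a block, 0 and 0 adjusted calls, 4564 probes at an unadjusted p below 0.05, and 1867 and 803 2-fold differences were found. Same-numbered arrays did not deviate together from their group means (r = −0.154, −0.123 and 0.0848 over probes). AMD3100 replicate 1 and saline replicate 2 dominated the deviations within their groups, so this cannot exclude that the numbers pair the samples.

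In all, 35 transcripts and probes were followed, each over up to 20 alternatives. Among those with an unadjusted limma p below 0.05 as reported, 1 changed sign: LOC102554996, at 0.016 with the detection covariate, near no difference. Detection parted the groups, so this covariate can take up part of their difference. In 27 of 688 values a transcript passed the adjusted threshold. Over 20 alternatives Rpph1 differed by 0.24 to 1.08 (limma adjusted p 0.0414 to 0.959), NONRATT015587 by −2.52 to −1.44 (0.0294 to 0.959). With no group overlap, leaving out an array could not change a sign. Filters and blocks left both estimates unchanged. The normexp offset shrinks differences of dim probes by construction, but the median signal was also used there. The 2 were not tested apart. Of 19 transcripts and probes with an unadjusted p below 0.05 as reported, 12 shrank at least 1.5 times with normexp: LOC102551612 to −0.26, NONRATT025109 to −0.24, A_64_P015727 to −0.57, A_64_P161399 to −1.09, A_44_P131311 to 1.27, XR_347830.2 to 0.80, Timm9 to −0.40, LOC102549197 to −0.60, LOC102549660 to −0.66, LOC102549737 to −0.39, LOC102549869 to −0.55 and LOC102554996 to −0.15. With the detection covariate 4 did: LOC102547708 to −0.68, LOC102549197 to −0.98, LOC102549737 to −0.66 and LOC102554996 as above. Spike-in scaling lowered every log2 difference by 0.64, so 6 of the higher ones shrank as much, among them Rpph1 to 0.24. Cb707485 (−1.37) was −0.32 in the second slide row alone and 0.73 with the covariate. The planned gene list tests and the mean over the probes of a gene were not run, since catalogue probes had no gene names here. Signal over background limits the lower differences: 520 probes were above it on all 3 saline arrays and on no AMD3100 array.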

Other observations

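Ftx, a lncRNA of the X-inactivation centre, was left out of the comparison because its only spot was marked as non-uniform on saline replicate 2. Its log2 signal relative to the 75th percentile was −2.45, −1.35 and −1.13 on the AMD3100 arrays and −0.58 and −0.56 on saline replicates 1 and 3, and it was picked out after its values were seen. The missing array is the one that correlated better with AMD3100 replicates 2 and 3 than with saline replicates 1 and 3. These values therefore do not show that the groups part.

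The test of brightness was set before its result was seen, and the look at other splits came after. Among the 2-fold differences, non-coding probes were lower more often than catalogue probes (86.4% against 63.6%), and a candidate explanation is the dimmer signal of the non-coding probes. This was tested within 4 equal groups of probes ranked by mean signal. The non-coding share exceeded the catalogue share in each, by between 17.7 and 26.8 percentage points, and in the brightest 52 of 65 non-coding differences were lower (80.0%) against 108 of 203 catalogue differences (53.2%). Brightness at the grain of these 4 groups therefore did not account for the gap. Signal can still differ between the classes within a group, which was not compared. The gap of 22.8 percentage points was 6.53 without AMD3100 replicate 2, 8.62 with the detection covariate, 14.2 with no filter, 1.04 with spike-in scaling, where nearly all differences were lower, and 21.6 to 27.7 otherwise. Another split, AMD3100 replicates 1 and 2 and saline replicate 2 against the rest, gave 43.8, so the gap was not limited to the split by treatment, and no biological explanation for it was tested.

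Leaving out saline replicate 2 gave 158 catalogue and 52 non-coding adjusted calls. Only 3 of these 210 probes were matched to a gene, each with a LOC name: LOC102547708, LOC102549197 and LOC102547473.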
